A study of Mus musculus with 14 samples.

How the data were processed

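Gene expression was measured by RNA sequencing in macrophages that had infiltrated the central nervous system of mice at the peak of experimental autoimmune encephalomyelitis, a mouse model of multiple sclerosis. Per the labels' protocols, irradiated hosts had received equal numbers of bone marrow cells from wild-type (wt) donors carrying the CD45.1 allele and from mCAT donors carrying CD45.2. mCAT donors combined a tamoxifen-inducible Cre recombinase at the Ccr2 gene with a Cre-dependent catalase directed to mitochondria. The titles give both as heterozygous (CCR2creERT2/+ and mcat lsl/wt). Monocyte-derived macrophages were sorted by donor marker, and libraries were made from polyadenylated RNA with Smart-seq2, a full-length method that keeps no strand information. There were 14 libraries, 7 of each genotype.

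The submitters' processing notes name FastQC, fastp and Salmon and the genome build GRCm39. Tool versions, the annotation and any filter on genes are not given in the sources used here. The deposited table is titled as raw counts, but its values are on a log2 scale: they hold no whole numbers, and all 14 libraries share 1 lowest value. They have the form of a variance-stabilising transformation of counts scaled between libraries. Undoing the closed form of that transformation, with the constant taken from the lowest value, gave what is called here the normalised count. The size of 1 read was set at the most frequent of the low normalised counts of each library. Between 56.3% (wt 7) and 77.8% of those low counts lay within 0.15 of a whole number of reads. Chance gives 30% for a size not fitted to the same values, so part of this excess was built in. Read depth is therefore a rough estimate, and whole reads were not recovered. Estimated depth ran from 16.6 M reads (M for mega) in wt 7 to 46.9 M in mCAT 1. Reads amplified without molecular identifiers are not independent molecules, so depth describes counting error only.

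The tests, gene lists, loci, alternatives and the rule for naming genes were chosen before the data were examined, except where stated. The chosen test was one for counts. Because the values turned out to be on a log2 scale, limma 3.58.1 in R 4.3.3 was run on the deposited values instead, with a mean-variance trend and robust variance moderation (statmod 1.5.0). The planned filter was also one for counts and was replaced. Genes were tested if their normalised count was at least 10 in at least 7 libraries, which kept 12096 of the 19940 genes. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Reported log2 differences are mCAT minus wt on the deposited scale, which compresses the differences of genes with low counts. Means and SDs are of normalised counts. On simulated data for these 12096 genes, drawn from the fitted stem effects and residual spread of each gene with the genotype effect removed, 67, 67 and 66 genes were shifted by 0.5, 1 and 2 on the log2 scale. The fit without pairing recovered 11.9%, 79.1% and 100% of them with 1 false call. With pairing it recovered 43.3%, 88.1% and 100% with 6 false calls.

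The library codes of 6 mCAT and 6 wt libraries share a stem, while wt 1 and mCAT 3 have no partner. Deviations from the group means, over the genes tested, correlated between the partners of all 6 stems, from 0.232 to 0.659, and 5 of the 6 pairs were each other's best match. The stem was therefore taken to pair the libraries, probably as macrophages of 1 host, although the labels do not state this. Numbers 4 to 7 in the titles join the same libraries as stems C1_5, C2_1, C2_2 and C2_4. Numbers 1 to 3 join other libraries, which correlated at -0.294, 0.158 and 0.252. The title numbers were not taken to pair the libraries. The planned fit had no pairing; the paired fit, with the stem as a block, is given beside a result where it changed a call. Libraries were treated as separate samples of a group; where partners come from 1 host, the unpaired p-values ignore this.

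Gene lists for 27 pathways and 16 cell types were tested with camera in limma at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. A list of fibroblast and pericyte markers, of which fewer than 3 were measured, was not tested. In simulations with no difference between genotypes, 23 of 860 list tests were called at the preset correlation, but simulated residuals were independent between genes, which those of real libraries are not. Cat, Ccr2 and Ptprc were compared by exact tests over all splits of 7 against 7 and over all sign flips of the 6 pairs. These exact tests, and those of the list means per library, were not part of the plan. Calls near Ptprc, Ccr2 and the Rosa26 locus (Gt(ROSA)26Sor) were counted within 10 Mb by 2-sided Fisher exact tests. Gene neighbourhood came from GENCODE M21 on GRCm38, which is not the build of the deposited values, so no coordinates are given. Called genes were compared with all transcripts of that annotation by blastn 2.17.0 to find copies of at least 95% identity over at least 50% of the transcript. Plots were drawn with matplotlib 3.10.9.

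Named genes followed a fixed rule: Cat, Ccr2 and Ptprc, the 12 called genes with the smallest p in each direction, and up to 4 members of each list with a call or up to 2 of another list. Predicted genes, marked pseudogenes and genes without a symbol were left to the counts unless stated. Alternatives covered the test, log scale, filter, pairing, library code prefix and leaving out each library. No per-sample column of the table was left unused.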

Results

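The series compared macrophages that differed in a mitochondrial catalase, an enzyme that breaks down hydrogen peroxide, in the inflamed central nervous system of mixed chimeras, and asked which genes differed with the genotype. Of the 14 libraries, 7 came from sorted wt (CD45.1) and 7 from sorted mCAT (CD45.2) monocyte-derived macrophages. Estimated depth was 27.7 to 46.9 M reads in mCAT and 16.6 to 43.1 M in wt libraries. Between 11874 and 12780 genes reached a normalised count of 10 in a library. The first principal component held 34.5% of the variance and the second 20.1%, and the genotypes overlapped on both. Libraries wt 6, mCAT 6, wt 7 and mCAT 7 lay at one end of the first component, and wt 1 stood apart at the other.

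Catalase transcripts did not pass the test between genotypes, whereas Ccr2, the chemokine receptor gene that carries the inducible recombinase, was lower in mCAT macrophages in the paired fit. Cat (ENSMUSG00000027187, chromosome 2) averaged 2155 ± 626 normalised counts in wt and 2831 ± 808 in mCAT libraries (mean ± SD, n = 7 each). Its log2 difference was 0.39 (SE 0.21), and an exact permutation test of 7 against 7 gave p = 0.128. Within the 6 pairs Cat was higher in mCAT in 6, by a median of 1.20-fold (exact sign-flip p = 0.0312, the smallest that 6 pairs allow), but its adjusted p over all genes was 0.390 in the paired fit. The source species of the added catalase is not given in the sources used here, so these values count only reads assigned to the mouse gene. Ccr2 (ENSMUSG00000049103, chromosome 9) averaged 13742 ± 5015 in wt and 8391 ± 2975 in mCAT (exact permutation p = 0.0262, n = 7 each). It was lower in mCAT in 6 of 6 pairs, at a median of 0.553 of the wt level, with an adjusted p of 0.878 without pairing and 0.00587 with it. Ptprc (ENSMUSG00000026395, chromosome 1), the gene of the CD45 marker used for sorting, stood at 10097 ± 3213 in wt and 10098 ± 1906 in mCAT (exact permutation p = 0.844, n = 7 each).

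**Figure D1:**
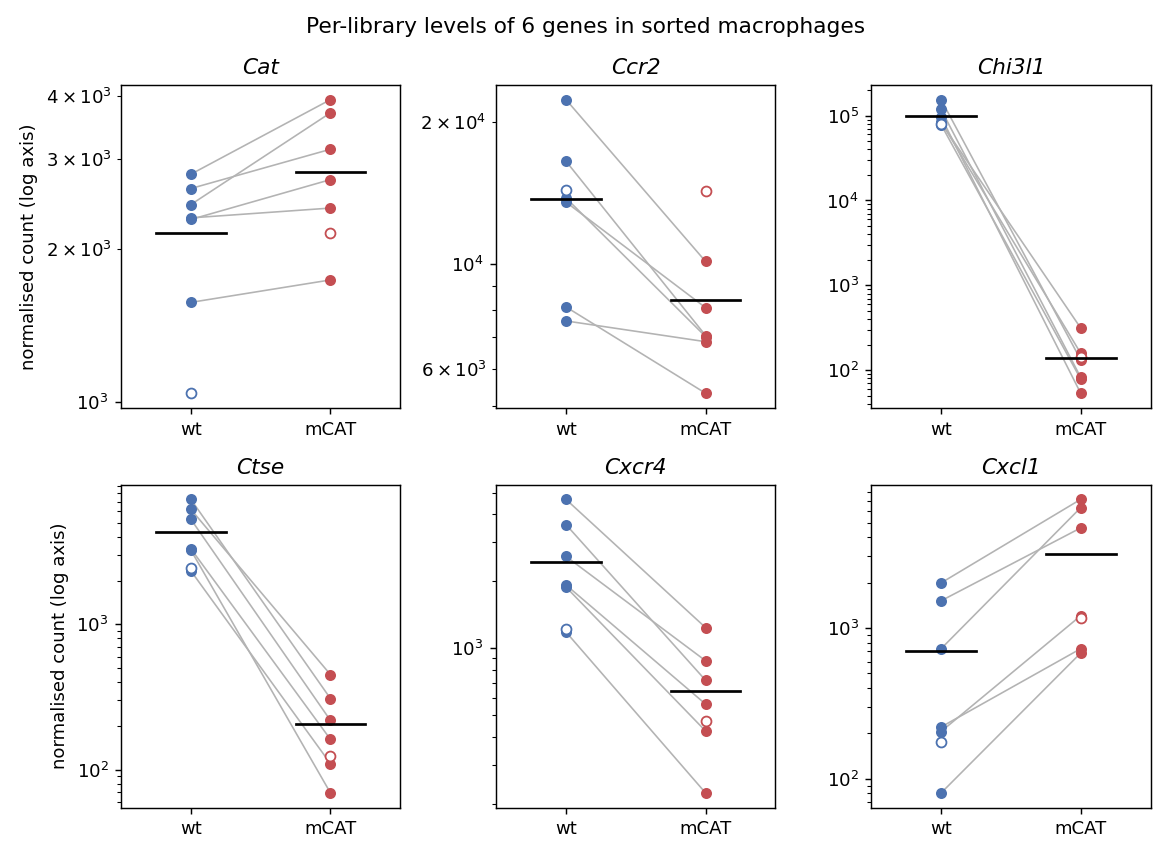
Normalised counts (log axes) of Cat, Ccr2, Chi3l1, Ctse, Cxcr4 and Cxcl1 in 7 wt (blue) and 7 mCAT (red) libraries; grey lines join the 6 pairs that share a library code stem, open circles are the unpaired libraries, and black bars are means. Chi3l1 and Ctse did not overlap between genotypes, and Cat and Cxcl1 were higher in mCAT in 6 of 6 pairs.

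Few genes differed between the genotypes, and the largest difference was that of a gene on chromosome 1. Of 12096 genes tested, 24 passed an adjusted p of 0.05, of which 10 were higher and 14 lower in mCAT macrophages; 649 had an unadjusted p under 0.05. Chi3l1 (ENSMUSG00000064246) encodes a secreted chitinase-like protein. It averaged 99186.5 ± 27971 normalised counts in wt and 138 ± 86.9 in mCAT, a 719.8-fold difference, and ranged from 53.6 to 314 over the mCAT libraries. Ctse (ENSMUSG00000004552), which encodes the aspartic protease cathepsin E, was 20.9-fold lower in mCAT (4294 ± 1947 against 206 ± 134). The chemokine receptor gene Cxcr4 (ENSMUSG00000045382) was 3.77-fold lower (2434 ± 1285 against 645 ± 335, adjusted p = 0.0323). Btg2, an antiproliferative gene induced early after stimulation, was 1.75-fold lower at a high level (87072 ± 16155 against 49817 ± 6158, adjusted p = 0.0224). All 4 genes were lower in mCAT in 6 of 6 pairs.

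Those 4 genes lie within 10 Mb of Ptprc, the locus at which the donors carry different alleles. Of 83 genes tested in that window 10 were called, against 14 of 11989 elsewhere (odds ratio 116, 95% confidence interval 44.8 to 293, Fisher exact p = 2.45e-16). In the paired fit, which called more genes elsewhere, the odds ratio was 56.2. Higher in mCAT among the 10 were Ppfia4 (28.4-fold, log2 difference 3.28, SE 0.25), the deubiquitinase gene Yod1 (4.41-fold) and Rab7b (2.34-fold), which encodes a GTPase of endosomal transport. Csrp1 (2.55-fold), Nav1 (3.18-fold) and Ptprv were lower; Nav1 was lower in 5 of the 6 pairs. Ptprv fell to 6.21 ± 7.51 normalised counts, near the lowest measurable level. No called gene lay within 10 Mb of the Rosa26 locus (0 of 101 tested) or, without pairing, of Ccr2 (0 of 68). The paired fit called 2 genes within 10 Mb of Ccr2, namely Ccr2 and the chemokine receptor gene Cxcr6 (odds ratio 9.79, Fisher exact p = 0.0203). Ccr2 is the targeted gene itself, so for its neighbourhood this count rests on Cxcr6 alone. Dag1, called in both fits, lies 15.9 Mb from Ccr2.

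**Figure D2:**
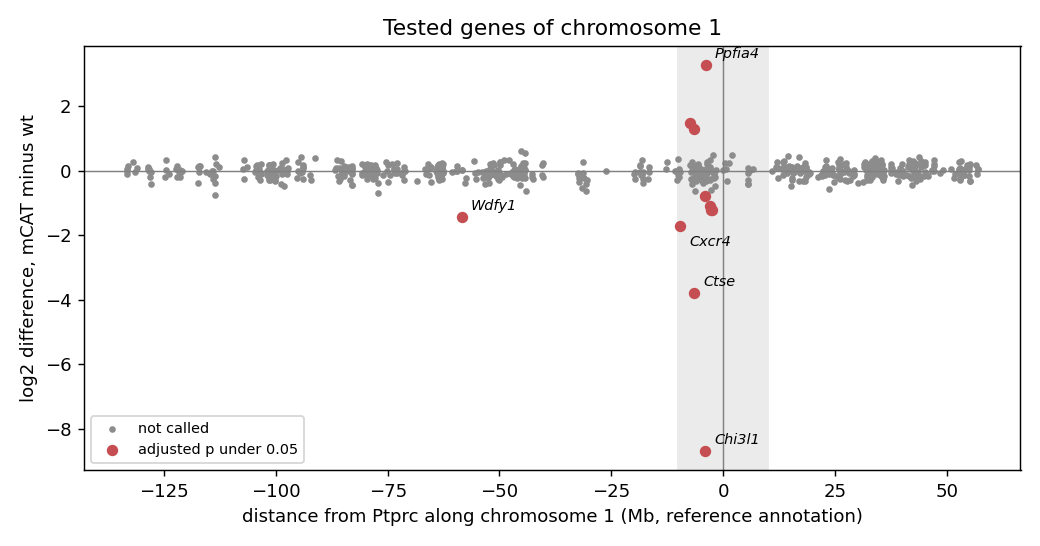
Log2 difference (mCAT minus wt) of every tested gene on chromosome 1 against its distance in Mb from Ptprc in the GRCm38 annotation; red points passed an adjusted p of 0.05 and the grey band spans 10 Mb on each side. Of the 11 red points 10 lie inside the band, and Wdfy1 lies 58.4 Mb away.

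The other 14 called genes were spread over several chromosomes, and none was a member of a gene list fixed here. Higher in mCAT were the centrosomal gene Cep85 (7.79-fold, 346 ± 50.4 against 2694 ± 730), Lrmda (6.43-fold), Dag1 (1.99-fold), which encodes the matrix receptor dystroglycan, Serpina3i, a serine protease inhibitor gene, and H2-Q7 (2.00-fold, 11684.5 ± 2939 against 23422 ± 3766), which encodes a non-classical MHC class I molecule. Lower in mCAT were Wdfy1 (2.83-fold), Map4k2 (2.77-fold), Hmgxb4 (2.87-fold), Abhd1 (2.80-fold), Dynlt1b (2.20-fold) and Rab4a, which encodes a GTPase of recycling endosomes and fell to 3.15 ± 2.84 normalised counts. Each of these 11 genes had the same direction in 6 of 6 pairs. Dynlt1b has copies of 98.8% to 99.2% identity to it in Dynlt1a, Dynlt1c and Dynlt1f, none of which passed the test, so how its reads were divided is uncertain. H2-Q7 also belongs to a family of closely related genes. The 3 remaining calls, named after their values were seen, were Gm16867 (51.5-fold higher), Gm15459 (67.5-fold higher) and Ermardl1 (2.20-fold lower), the last 2 of which are near-identical to other genes.

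Several calls lay close to the threshold. Leaving out 1 of the 14 libraries ended the call of Cxcr4 and of Rab7b in 10 cases each (adjusted p up to 0.0939 without mCAT 4 and 0.120 without mCAT 1), and that of Btg2 in 8 (up to 0.0754 without wt 3). It ended the call of Dag1 in 5 cases (up to 0.0680 without wt 4), of Serpina3i in 4 (up to 0.0555 without wt 5) and of Ermardl1 in 11 (up to 0.102 without wt 4). All 6 were called in the paired fit.

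With the libraries paired, 39 genes passed, 20 higher and 19 lower in mCAT, including all 24 of the unpaired fit. Of the 15 added genes, all but Ccr2 and Cxcl1 are named after their values were seen. The neutrophil chemokine gene Cxcl1 averaged 703 ± 761 normalised counts in wt and 3118 ± 2815 in mCAT and was higher in 6 of 6 pairs (paired log2 difference 1.96, SE 0.16, adjusted p = 6.76e-06). The related genes Serpina3f (0.83) and Serpina3g (0.50), the lysosomal glycoprotein gene Gpnmb (0.48), the collagenase gene Mmp8 (0.47), H2-Q6 (0.98), Esr1 (0.63), Cadm1 (1.21) and Gpr137b (0.52) were also higher in 6 of 6 pairs on the log2 scale. Ide was higher in 5 of 6 pairs. Ccr2, Cxcr6 (-0.76), the fatty acid binding protein gene Fabp7 (-0.74), Suco (-0.55) and Srp54b (-0.50) were lower in 6 of 6 pairs. Several of the added calls lay close to the threshold. In the paired fit adjusted p was 0.0492 for Cxcr6, 0.0469 for Suco, 0.0379 for Ide, 0.0363 for Gpnmb and 0.0343 for Mmp8, and lower for the others. Srp54b has copies of 99.6% identity in Srp54a and 99.7% in Srp54c, so its reads are uncertain too. H2-Q6 is of the same family as H2-Q7, but the search found no copy of it at the identity and length set. Without pairing none of these 15 passed, with adjusted p from 0.0793 for H2-Q6 to 0.887 for Mmp8.

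Genes of hydrogen peroxide handling and its known responses showed no called member. Of 22 measured genes of hydrogen peroxide and superoxide detoxification, 1 was lower when adjusted over the list alone, the mitochondrial glutaredoxin gene Glrx2 (983 ± 104 against 707 ± 108, log2 difference -0.42, list-adjusted p = 0.0283), and it was lower in 6 of 6 pairs. Over all genes tested its adjusted p was 0.412, and it lies 5.61 Mb from Ptprc. With pairing, adjusted over the list alone, Glrx2 and the peroxiredoxin gene Prdx2 were lower (6749 ± 840 against 5336 ± 650, list-adjusted p = 0.0381) and Cat was higher (list-adjusted p = 0.0472). The list as a whole had a median log2 difference of -0.04 (camera adjusted p = 0.430). None of 20 NRF2 target genes, 19 integrated and mitochondrial stress response genes or 6 NADPH oxidase genes passed either adjustment. Their medians were 0.08, -0.03 and 0.07, with camera adjusted p of 0.693, 0.693 and 0.667.

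Respiratory chain and ribosomal transcripts were slightly lower in mCAT as lists, without a called member. Of 43 lists tested 5 were called at the preset correlation, 0 with an estimated correlation and 0 by fry's test of direction. Fry's mixed test, for changes in either direction, called 0 without pairing and 8 with it. Those 8 were the chemokine, p53, iron, adhesion, immediate early, macrophage, classical monocyte and T cell lists. Such a test can be carried by 1 strong member. Members called in the paired fit were Cxcl1 (chemokine), Btg2 (p53 and immediate early), Cxcr4 and Ccr2 (adhesion) and Gpnmb (macrophage). Of these, Btg2 and Cxcr4 lie within 10 Mb of Ptprc. The iron, classical monocyte and T cell lists held no called member. The 52 nuclear-encoded oxidative phosphorylation genes had a median log2 difference of -0.21, with 9 of 52 above 0 (camera adjusted p = 4.52e-13, but adjusted p = 0.773 with an estimated correlation). Its mean per library was lower in mCAT in 6 of 6 pairs (exact permutation p = 0.00758 for 7 against 7, adjusted over 43 lists 0.163). The smallest p-values were those of Ndufs4 (3644 ± 760 against 2612 ± 486), Cox7a2, Atp5f1e and Ndufs6, each at 0.0796 when adjusted over the list alone. All 12 measured mitochondrially encoded genes lay below 0, with a median of -0.42 (camera adjusted p = 1.67e-05, but adjusted p = 0.922 with an estimated correlation). In wt 1 this list stood 1.28 above its mean over the libraries, and it was lower in mCAT in 3 of the 6 pairs, with a median of -0.20 in the paired fit. All 25 ribosomal protein genes lay below 0, with a median of -0.25, and -0.16 in the paired fit (camera adjusted p = 7.22e-10, but adjusted p = 0.922 with an estimated correlation), Rpl27 (5491 ± 670 against 4361 ± 793) having the smallest p. None of these respiratory chain and ribosomal lists had a member that passed over the list alone.

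Markers of T cells were lower in mCAT libraries as a list, with scarce members lower and the most abundant one higher. The list had a median log2 difference of -0.39 (camera adjusted p = 8.55e-07, but adjusted p = 0.564 with an estimated correlation). Over all genes none of the 13 measured markers passed, and 7 were lower when adjusted over the list alone. They included the T cell receptor complex gene Cd3g (61.1 ± 24.8 normalised counts in wt, 20.1 ± 10.1 in mCAT), the kinase gene Lck (141 ± 63.7 against 55.2 ± 29.6) and the adhesion gene Cd2 (101 ± 46.1 against 48.4 ± 24.6). The interleukin 7 receptor gene Il7r, singled out after its values were seen, averaged 3496 ± 1425 in wt and 4309 ± 1751 in mCAT (list-adjusted p = 0.0194 with pairing). It was higher in 6 of 6 pairs, and because of it the summed counts of the list were higher in mCAT in 5 of 6 pairs. With pairing 6 markers were lower and 1 higher when adjusted over the list alone. Its mean per library was lower in mCAT in 6 of 6 pairs, with a mean pair difference of -0.26 ± 0.11 on the log2 scale (SD, exact sign-flip p = 0.0312, adjusted over 43 lists 0.224). Over 7 against 7 the exact permutation p was 0.00699, adjusted 0.163. B cell markers were called lower only in the paired fit (camera adjusted p = 3.35e-04, but 0.589 as adjusted p with an estimated correlation), with 5 of 9 lower when adjusted over the list alone. Natural killer cell markers were not called (camera adjusted p = 0.109, 5 measured), with a mean lower in mCAT in 6 of 6 pairs.

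**Figure D3:**
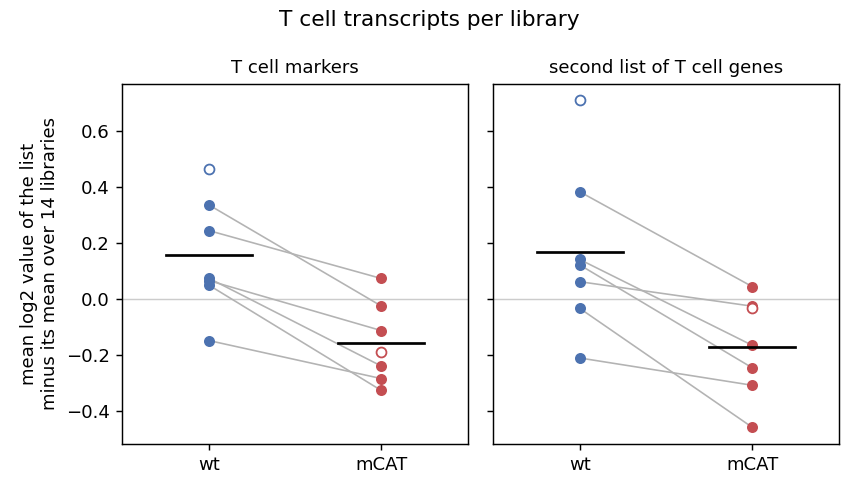
Mean log2 value of the T cell markers (left) and of a second list of T cell genes (right) in each library, minus the mean over the 14 libraries, by genotype; lines join pairs, open circles are unpaired libraries and black bars are means. Both lists were lower in mCAT in 6 of 6 pairs.

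Genes of lipid handling in macrophages were slightly higher in mCAT as a list. All 20 measured genes of lipid uptake, storage and cholesterol efflux lay above 0, with a median log2 difference of 0.20 (camera adjusted p = 0.0212, but adjusted p = 0.922 with an estimated correlation). No member passed either adjustment. The smallest p-values were those of the lipogenic regulator gene Srebf1 (1281 ± 363 against 1710.2 ± 268), Soat1, Abcg1 and Lpcat3. Without wt 1, in which the list stood at -0.71 against its mean over the libraries, the camera adjusted p was 0.193. The call also ended without wt 3, wt 4, mCAT 6 or mCAT 7, at adjusted p of 0.0929, 0.0834, 0.108 and 0.134. In the paired fit, where wt 1 has no partner, the list was called (camera adjusted p = 0.00100, but 0.553 with an estimated correlation). Its mean per library was higher in mCAT in 6 of 6 pairs (exact sign-flip p = 0.0312, adjusted over 43 lists 0.224). In the paired fit, markers of monocyte-derived macrophages (camera adjusted p = 0.00100) and lysosome and phagocytosis genes (0.00765) were also called higher, with adjusted p of 0.553 and 0.790 with an estimated correlation. Gpnmb was the called member in both.

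Among the lists of adhesion receptors, p53 and apoptosis genes and immediate early genes, 1 member each was called. Camera called none of them as a list (camera adjusted p of 0.485, 0.485 and 0.693), while fry's mixed test called each with pairing. Of 17 adhesion and migration receptors Cxcr4 was lower, and adjusted over the list alone the integrin gene Itgam was higher (16822 ± 4654 against 24794 ± 3996). Btg2 was the called member of both other lists. Cxcr4, Btg2 and Phlda3 lie within 10 Mb of Ptprc, and Itgam does not. Of 18 p53 and apoptosis genes, Phlda3 was higher when adjusted over the list alone (24.6 ± 12.5 against 59.9 ± 16.3), and with pairing Ccng1 was also higher and Bcl2 also lower. With pairing Ccr2 was a second lower member of the adhesion list. Among the 19 immediate early genes Fos averaged 183158 ± 39157 in wt and 209563 ± 15391 in mCAT, with an adjusted p of 0.878.

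No list of inflammatory, interferon or antigen presentation genes passed the test without pairing, and all varied between libraries. No member of the lists of inflammatory cytokines (18 measured), NF-kappaB feedback targets (21), type I interferon response (33), interferon gamma response (22) or MHC class II presentation (13) passed either adjustment without pairing. Of 21 chemokines none passed without pairing, and Cxcl1 did with it. With pairing, adjusted over the list alone, Cd74 and the MHC class II activator gene Ciita were higher. Of the NF-kappaB targets 1 was then higher and 1 lower (Bcl2a1a). The median log2 differences of those first 5 lists were 0.02, -0.05, -0.07, 0.01 and 0.07. The cytokine gene Il6 averaged 4874 ± 1868 in wt and 3882 ± 1980 in mCAT, and Cd74, the MHC class II invariant chain gene, 197835 ± 46469 and 271587 ± 73235. Not called either, with their median log2 differences, were the lists of glycolysis and hypoxia (0.06), TCA cycle and fatty acid oxidation (-0.01), mitochondrial dynamics and mitophagy (0.03), cholesterol biosynthesis (0.10), alternative activation (0.07), matrix remodelling (0.16), inflammasome (-0.03), iron handling (-0.01) and cell cycle genes (0.06).

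Markers of other cells that a sort from the central nervous system could hold showed no call without pairing apart from those of T cells. Median log2 differences were 0.05 for microglia, 0.02 for border-associated macrophages, -0.04 for classical and 0.09 for non-classical monocytes, and 0.24 for neutrophils. They were -0.09 for conventional and 0.02 for plasmacytoid dendritic cells, -0.09 for oligodendrocytes, -0.07 for astrocytes, -0.11 for neurons, 0.10 for endothelial cells and -0.11 for erythroid cells. With pairing, adjusted over the list alone, the classical monocyte markers S100a4 and F13a1 were lower and higher, Mmp8 was higher among neutrophil and matrix genes, and 1 iron handling gene was lower. The median and the mean differed in sign for inflammatory cytokines, chemokines (median -0.07), TCA cycle, iron handling, microglia and plasmacytoid dendritic cell lists.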

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

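The rule was fixed in advance. Among 68 sets of 7 libraries (named genes, library measures and gene lists), 4 held a library whose gap to the nearest other exceeded Dixon's 95% critical value for that gap as a share of the range; chance gives about 1 in 20. For genes the rule was applied to the deposited log2 values, while normalised counts are printed here. Dag1 stood at 1082 normalised counts in mCAT 6, while the other mCAT libraries held 589 to 744. Hmgxb4 stood at 622 in wt 7, the library of lowest estimated depth, against 400 to 480 in the other wt libraries. Abhd1 stood at 26.7 in mCAT 5, against 52.9 to 75.3 in the other mCAT libraries. The estimated depth of mCAT 4 was 27.7 M reads, against 41.2 to 46.9 M in the other mCAT libraries.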

How the results depend on the processing

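The log2(normalised count + 1) scale, the locus counts without wt 1 and the paired fits without wt 1 or wt 7 were chosen after seeing the data; the others were set before. The count of 24 genes stayed between 18 and 25 when 1 library was left out, and between 20 and 27 under the other tests, log scale and filters, with the title numbers as a replicate block and with the code prefix as a covariate. Median ratio scaling gave 1 factor for all 14 libraries, so it tested nothing and is not counted here. Without wt 1 it was 25, with all 24 genes among them. Pairing by code stem gave 39 genes, 38 with the 6 complete stems only, 38 without wt 1, 28 without wt 7 and 37 on the log2(normalised count + 1) scale. Unpaired libraries do not enter the paired log2 differences, so leaving out wt 1 or mCAT 3 could hardly change this count. Of these fits, only that without wt 7 removed a pair. Fewer libraries called fewer genes, 15 with prefix C1 and 9 with prefix C2. The number of lists was 5, and 4 to 9 with 1 library left out: 8 without mCAT 3 and 9 without wt 6 or without wt 7. It was 8 with pairing and 0 with an estimated correlation. The causes were not tested. The odds ratio near Ccr2 was 0 without pairing, 2.82 within 20 Mb and 9.79 with pairing, where Ccr2 itself was among the calls. That near Ptprc was 111 within 5 Mb, 60.2 within 20 Mb and 109 without wt 1. The log2 difference of Cat stayed between 0.23 and 0.49. Of the comparisons of named genes with alternatives, 2142 kept their side of the threshold, 49 lost a call and 17 gained one. None changed direction with a call in either fit, while some uncalled genes changed sign. Most of these genes were not called in the main fit and had no call to lose. The 49 losses all fell on Cxcr4, Rab7b, Btg2, Dag1, Serpina3i and Ermardl1. Pairing changed the calls given beside the results, including the counts adjusted over the list alone in 14 lists. The count tests planned with negative binomial models were not run, since the values are not counts. At the simulated spread the unpaired fit found few shifts of 0.5, so small differences could go uncalled.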

Other observations

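Of the tests in this part, those on Hspa8, the second T cell list, gene length and wt 1 were chosen after the pattern was seen and before their own value was; the counts on other chromosomes were chosen after their result was seen. Type I interferon genes and markers of macrophages and microglia varied widely between library code stems, a spread noticed in the data and not tested. Averaged over the libraries of a code stem, the type I interferon list stood -0.81 and -0.90 from its mean over all libraries (log2 scale) in stems C2_2 and C2_4, against 0.72 in C1_5 and 0.61 in C2_1. Markers of monocyte-derived macrophages stood 0.53 and 0.57 above their mean in C2_2 and C2_4, 0.12 above it in C2_1 and below it in all C1 stems. Microglia markers went the same way, at 0.64, 0.58 and 0.28 in those C2 stems and from -0.22 to -0.52 in the C1 stems. Lipid handling genes stood at 0.48 and 0.41 in C2_2 and C2_4, and classical monocyte markers at -0.94 and -0.47. The labels give no treatment that differs between these stems, and no explanation was tested.

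Library wt 1, which has no mCAT partner, held the highest type I interferon (0.73) and classical monocyte (0.73) values among the code stems. It also held the lowest macrophage marker value (-1.03) among them. Most stems average 2 libraries, and for type I interferon wt 4 alone stood higher, at 0.80. In wt 1 the erythroid markers stood 2.04 and the mitochondrially encoded genes 1.28 above their means over the libraries. Transcripts of the Y-linked gene Ddx3y reached 30.9 normalised counts in mCAT 3 and 15.3 in mCAT 4, and 9.86 or less in the other libraries. The Y-linked genes Uty and Kdm5d were also highest in mCAT 4 and mCAT 3. Eif2s3y was instead highest in wt 2 (17.2), against 12.5 in mCAT 3 and 5.5 in mCAT 4.

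Of 100 splits of the 14 libraries into 7 and 7, 4 called at least the 24 genes of the genotypes, the real one included. That share was just under the bound set beforehand, which makes chance less likely but does not exclude it. The others parted 0 or 1 pairs where the real one parted 6. They called 519 and 334 genes with all 6 libraries of code prefix C2 on one side, and 76 with 4 of them. Such counts point to a structure of the samples, in the first 2 along the prefix, whose meaning is not given. With the prefix as a covariate 27 genes were called, the 24 among them. Of 32 swaps within the pairs 1, the real one, called as many as its 39 genes (highest other 1), the smallest share these swaps allow. The odds ratio of 116 near Ptprc fits a congenic segment that came with the CD45 allele for 10 genes, among them Chi3l1, Ctse and Cxcr4. The design confounds such a segment with the catalase, and its length is not given, but it cannot hold the 13 called genes on other chromosomes. All wt cells came from CD45.1 and all mCAT cells from CD45.2 donors. For those 13 genes too, other inherited differences between the donors are therefore confounded with the catalase. Strain sequence beside Ccr2 or the Rosa26 locus cannot hold the 23 and 24 called genes on other chromosomes. The 0 calls within 10 Mb of each without pairing exclude little, as the odds ratio intervals are wide. For Dag1, 15.9 Mb from Ccr2, and for Cxcr6 in the paired fit it stays open. Cxcr6 was highest in wt 1 (219) and wt 3 (193), which also stood highest on both T cell lists. Less T cell RNA in mCAT libraries, taken up below, therefore stays open for Cxcr6 too and was not tested. Ccr2 itself carries the heterozygous insertion in mCAT donors, so its lower level cannot tell strain sequence from the insertion. Gm15459, a 99.7% identical copy of the chaperone gene Hspa8, held 9.17% to 12.6% of their summed counts in mCAT and 0.115% to 0.382% in wt, which may come from an Hspa8 variant of 1 donor strain, but Hspa8 was lower in mCAT in only 4 of 6 pairs and that test did not decide.

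Lower T cell markers in mCAT libraries may come from less T cell RNA carried into those sorts. Il7r, higher in mCAT in 6 of 6 pairs, was far more abundant than Cd3g, Lck or Cd2. Which cells it came from was not tested, so its rise does not argue against less T cell RNA. A second list of 19 T cell genes, chosen after the first list was seen and before these genes were looked at, had 14 measured members, all lower in mCAT, with a median log2 difference of -0.36 (exact permutation p = 0.0181, n = 7 each; 6 of 6 pairs lower). Its members were scarce, and the most abundant, Ms4a4b, averaged 452 normalised counts in wt and 336 in mCAT. Fewer T cells or less free RNA in the CD45.2 gate, and a lower level within macrophages, remain open, and a link to catalase was not tested.

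The number of lists called, among them respiratory chain, ribosomal, T cell and lipid genes, was no larger than other groupings of the libraries gave. Few groupings parted the T cell and nuclear oxidative phosphorylation lists as far on their own (exact permutation p = 0.00699 and 0.00758, n = 7 each, each 0.163 adjusted over 43 lists). For the ribosomal, mitochondrially encoded and lipid lists the exact permutation p was 0.0828, 0.16 and 0.345. Of 100 splits of the libraries, 93 called at least the 5 lists of the genotypes (highest other 21), and of 32 swaps within pairs 10 called at least the 8 of the paired fit (highest other 15), so chance cannot be excluded for these numbers. Of 10000 random lists matched on gene length and expression level, 0% had a median as low as the -0.21 of the oxidative phosphorylation list, and their own median was -0.06. The random genes were drawn independently, while those of the list correlated with each other (estimated correlation 0.299). Length was taken over all annotated exons rather than over the transcript expressed. The test therefore does not decide whether length or level is a cause. Without wt 1, 4 of the 5 lists were still called in the unpaired fit and the lipid list was not (camera adjusted p = 0.193). That result lay between the bounds set for the test, so the part played by wt 1 stays open. The paired fit, where wt 1 has no partner, called the lipid list (camera adjusted p = 0.00100, but 0.553 with an estimated correlation). A biological difference from the catalase was therefore not separated from other differences between libraries.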
